A study of Drosophila melanogaster with 4 samples.

How the data were processed

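ChIP-seq with the Sfmbt antibody Q2642 was done on cross-linked, sonicated chromatin of adult Drosophila melanogaster heads, with 2 ChIP replicates and 2 inputs, per the labels' protocols. The labels name input replicate 1 as the input of the first list and input replicate 2 as that of the second. Bowtie 0.12.7 is named in the submitters' processing notes. The coordinates are those of FlyBase release 5, per the file headers. The peak caller, its threshold, any filter on duplicate or multiply mapped reads and the way the replicates were combined are not given in the sources used here. Repeats and collapsed copies can raise or hide enrichment, and how reads from them were treated decides values on heterochromatic and unplaced sequence.

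The authors deposited 1 list of regions of significant enrichment for each ChIP replicate, called per sample, and 1 for the replicate set. Each region has a start, an end and 1 score. The deposited scores are log2 values, which was settled from the values and is stated in no header or label. Taken as powers of 2 and divided by 1 constant per list, they came out as ratios of whole numbers (denominator up to 3000, relative tolerance 1e-11) for 91.2% of clusters in replicate 1, 98.7% in replicate 2 and 99.8% in the combined list. Random scores did so for at most 0.14%, and no constant was found for base e or base 10. What the whole numbers count is not stated, so they were not used as read counts and the depth per sample is unknown. The score is the authors' own value for a cluster. It was used to describe, rank and filter clusters and compare arms within a list, and to compare replicates over shared clusters. The constant of each list sets an offset between lists, which enters SDs between replicates, so counts of clusters that differ are also given with the median difference subtracted.

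Lists were read as deposited, and no cluster was removed. No list held overlapping or repeated clusters. Overlap meant at least 1 shared bp. The reproducible set was the combined-list clusters with an overlapping cluster in both replicates, and a replicate's score for such a cluster was that of its highest-scoring overlapping cluster. Arm lengths came from the file headers. Overlap was tested against 10000 random placements of the other list within its arms, clustering by the variance to mean ratio of cluster midpoints in 100 kb windows against 10000 placements, and X density against 10000 placements over the main arms. Score correlation was tested with 100000 permutations of the pairings. Alternatives used 1000 placements. P-values add 1 to both counts, and Benjamini-Hochberg adjustment was over 7 tests. Shares carry 95% exact (Clopper-Pearson) intervals, which cover counting error only. The comparisons of X scores and of chromosome 4 were added after the data were seen, with 1 Mb blocks of sequence permuted for the X and clusters reassigned to arms by length for chromosome 4.

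The regions named were chosen before the data were examined, as the 20 highest-scoring reproducible clusters, the 5 windows of 100 kb with the most clusters and the widest cluster of each arm, with ties ordered by arm and start. The other tests, the gene lists and most alternatives were also fixed then, and sensitivity to settings chosen later is given with the results. Shares of clusters at transcription start sites, 13 gene lists and motif density were planned for a genome or annotation of release 5, and were not run, because the gene table at hand is of release 6 and coordinates were not converted. The analysis used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. On simulated data, an overlap planted in 60.0% of 6359 clusters was recovered as 59.5%. The planted clusters were shifted by less than their width, and the chance overlap of the clusters known to be random was subtracted. That recovery was therefore set by construction and checks the counting only. The clustering test called 2 of 100 random placements of 8157 clusters (the number of the combined list on the main arms, more than in the reproducible set). The 1 Mb block test found an X density 1.5 times higher in 100 of 100 simulations and made 3 false calls of 100. The block simulations placed clusters independently, whereas the real clusters are unevenly spread. Their false-call rate therefore need not hold for the data, and power at smaller ratios was not measured.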

Results

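Sfmbt (labelled dSFMBT) is a Polycomb group protein of Drosophila melanogaster. It forms the Pho repressive complex with the DNA-binding protein Pho, and its MBT repeats bind methylated histone tails. Its genomic sites were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei of adult heads from the wild-type Oregon-R strain, with the antibody Q2642. The series holds 4 samples, which are 2 ChIP replicates and 2 input chromatin samples, 1 input for each ChIP. The values analysed were 3 lists of enriched clusters, 1 for each ChIP replicate and 1 for both replicates combined. Each cluster has a position in FlyBase release 5 and a score, which is the authors' and is on a log2 scale. The inputs entered through the calling of the clusters, and their own signal was not analysed here. Read depth is unknown, and the labels do not say whether the 2 ChIP samples came from separate collections of flies, so the spread between them may be technical.

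Sfmbt clusters lay on every main chromosome arm, were mostly narrow and covered a similar share of the genome in both replicates. Replicate 1 had 6560 clusters and replicate 2 had 6508. The median width was 2245 bp in replicate 1, with quartiles of 1981 and 2995 bp, and 2213 bp in replicate 2. The clusters covered 14.7% of the main arms (2L, 2R, 3L, 3R, 4 and X) in replicate 1 and 14.2% in replicate 2. The median score was 0.79 in replicate 1 and 0.76 in replicate 2, and the highest was 4.67 and 4.44. Wider clusters had higher scores, with a Spearman rho across clusters of 0.738 in replicate 1 and 0.724 in replicate 2. The combined list had 8434 clusters that covered 19.2% of the main arms. Its median score was 0.59, on a scale that is not set against those of the replicates.

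The first comparison asked whether the same sites were enriched in both replicates. Most were. Of the clusters of replicate 1, 5765 of 6560 (87.9%, 95% exact binomial interval 87.1 to 88.7%) overlapped a cluster of replicate 2 by at least 1 bp. In the other direction, 5824 of 6508 (89.5%, interval 88.7 to 90.2%) overlapped. Random placement of the other replicate's clusters within their arms gave means of 24.6% and 24.8%, and the highest of 10000 placements were 26.5% and 26.95%. The one-sided p of 0.0001 was in each case the smallest that the placements could give, and it was 0.00014 after Benjamini-Hochberg adjustment over the 7 tests of this kind. Random placement does not keep the uneven spacing of clusters. Circular shifts of whole arms gave means of 25.9% and 26.4%, and the highest of 1000 shifts were 37.2% and 37.9%. Gene density and mappability were not controlled for. Strong clusters were shared almost without exception. Of the 10% of clusters with the highest scores in replicate 1, 99.1% (interval 98.02 to 99.66%) were found in replicate 2, against 69.5% (interval 65.8 to 73.02%) of the 10% with the lowest scores. For replicate 2 these shares were 99.2% and 74.3%. The 795 clusters of replicate 1 without a partner had a median score of 0.54, against 0.84 for those with one. The 684 without a partner in replicate 2 had a median of 0.56, against 0.80. No cluster had identical coordinates in the 2 lists.

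**Figure D1:**
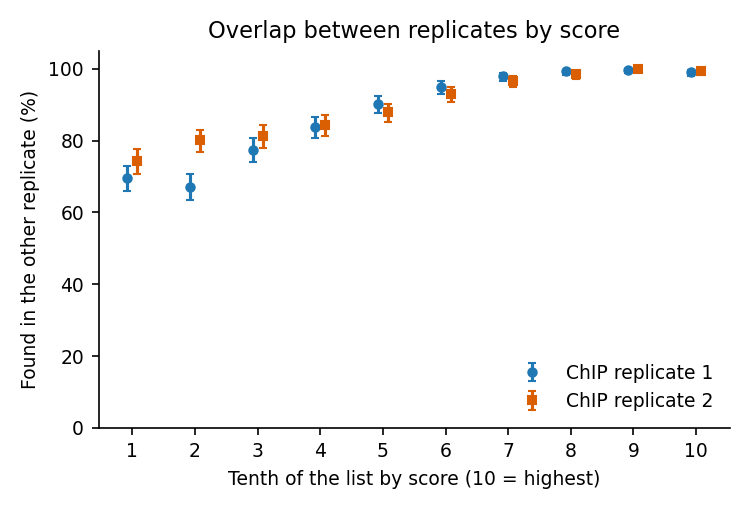
Percentage of each replicate's clusters that overlap a cluster of the other replicate, in 10 equal groups of the list ranked by score (10 holds the highest scores). Points are shares and bars are 95% exact binomial intervals; the share was 69.5% in the lowest group of replicate 1 and 99.1% in its highest.

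The scores of shared clusters rose together. Across the 5765 clusters of replicate 1 with a partner, Spearman's rho with the score in replicate 2 was 0.801 and Pearson's r was 0.816. A two-sided permutation of the pairings gave p = 1e-05 for both, the smallest that 100000 permutations could give, and clusters within 1 pair of libraries are not independent replicates. Among the 5329 clusters with 1 partner each way, the score in replicate 1 exceeded that in replicate 2 by a mean of 0.05, with an SD of 0.21 between clusters. Each list carries a scaling constant of its own, so an offset between lists has no meaning by itself. Replicate 1 was higher by more than 0.5 at 191 clusters, and replicate 2 at 10. With the median difference of 0.03 subtracted, these counts were 173 and 17. At those 191 clusters the mean score was 1.63 in replicate 1 and 0.93 in replicate 2.

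**Figure D2:**
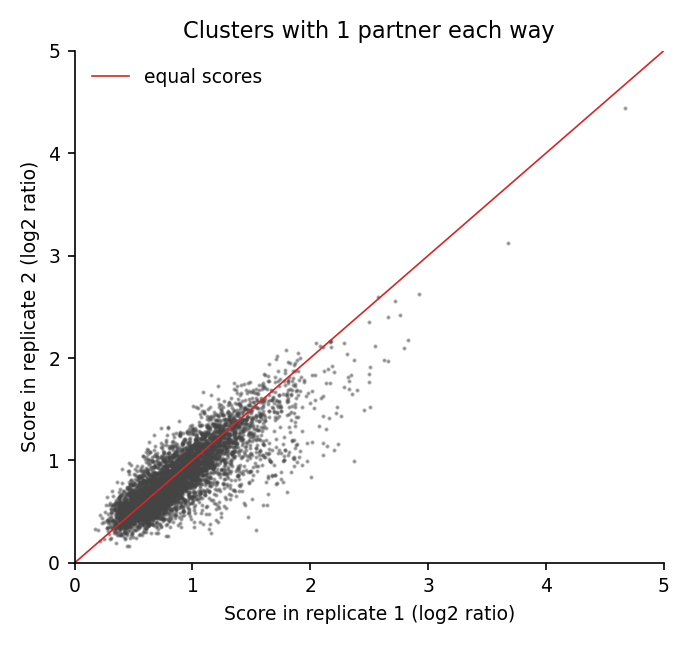
Score of each of the 5329 clusters with 1 partner each way, in replicate 1 (x axis) and replicate 2 (y axis), both as log2 ratios. The line marks equal scores; 191 points lie more than 0.5 to the replicate 1 side and 10 to the replicate 2 side.

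The tests of location used the 5493 clusters of the combined list (65.1%, exact interval 64.1 to 66.1%) that overlapped a cluster in both replicates, called the reproducible set. Values given as a mean and SD by arm came from each replicate's own list. They had a median width of 2679 bp and a median score of 0.78, and 5405 of them lay on the main arms, where they covered 15.3% of the sequence. Another 733 combined clusters overlapped replicate 1 alone, 618 replicate 2 alone and 1590 neither. Their median scores were 0.37, 0.38 and 0.41. Not every cluster outside the reproducible set scored low. Exact scores of 3.29, 3.14 and 2.97 were held by 2, 4 and 6 clusters, and the reproducible set has none at these scores.

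The strongest reproducible sites were clusters on 2R, 3L, 3R and X, together with a site on heterochromatic sequence and a site on unplaced sequence. The strongest lay on 3RHet (2348172 to 2350876), with a score of 4.55 ± 0.16 (SD, n = 2) in the replicates. The 20 highest-scoring clusters were 2233 to 3919 bp wide. Their median width of 2614 bp was close to the 2679 bp of the reproducible set. Of them, 7 lay on the X, 5 on 3R, 4 on 2R, 2 on 3L, 1 on 3RHet and 1 on U, the collection of unplaced sequence. None was on 2L or chromosome 4. Replicate 1 gave the higher score at 19 of the 20, and at 18 with the median difference between the lists subtracted. Genes are not assigned to these sites, because the gene table at hand describes release 6.

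On the X, 4 of the 5 main-arm reproducible clusters with the highest combined scores fell within 599 kb. By the mean of the replicates the cluster at 5800044 ranked lower. The cluster at 5417192 to 5419925 scored 3.68 in replicate 1 and 3.13 in replicate 2 (SD 0.39, n = 2), that at 5505950 to 5508514 scored 2.77 ± 0.22 and that at 5204780 to 5207821 scored 2.64 ± 0.11. The cluster at 5800044 to 5803374 scored 2.44 ± 0.86, with 3.04 in replicate 1 and 1.83 in replicate 2, the widest gap among the 20. A further pair lay within 19.0 kb, at 17644695 to 17647038 (2.33 ± 0.30) and 17661124 to 17663666 (2.13 ± 0.52). The last X cluster of the 20, at 3027567 to 3030785, scored 2.17 ± 0.46.

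On 3R, 3 of the 20 lay within 712 kb. They were at 12794122 to 12796818 (2.59 ± 0.012, SD, n = 2), 12085198 to 12087860 (2.43 ± 0.10) and 12693825 to 12696386 (2.18 ± 0.19). The widest cluster of 3R, 32802 bp long at 12045877 to 12078678, ended less than 10 kb before the second of these and had a combined score of 1.26. The other 3R sites were at 677011 to 679491 (2.45 ± 0.49) and 7437928 to 7440160 (2.21 ± 0.42). On 2R the clusters at 20072682 to 20076600 (2.59 ± 0.24), 12686618 to 12688865 (2.32 ± 0.49), 21069500 to 21071885 (2.30 ± 0.45) and 11226022 to 11228895 (2.21 ± 0.10) were among the 20. On 3L these were the clusters at 6896045 to 6898437 (2.53 ± 0.18) and 2850809 to 2853115 (2.50 ± 0.46). The site on U, at 9287499 to 9290352, scored 2.16 ± 0.0069.

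Sfmbt clusters lay in groups along the arms. The 1202 windows of 100 kb held a mean of 4.49 reproducible clusters, 96 windows (7.99%) held none and 60 held 10 or more. The variance to mean ratio was 1.97, against a mean of 1.03 and a highest value of 1.20 over 10000 random placements within arms. The one-sided p of 0.0001 was the smallest possible, and the adjusted p was 0.00014. Placements could fall anywhere on an arm, including sequence with few genes or where reads cannot be mapped. Gene density and mappability were not controlled for, so the test does not separate grouping of sites from uneven sequence. The fullest window, 3R 5300001 to 5400000, held 15 clusters that covered 38.4% of it, and each replicate's own list also had 15 there. The windows 2L 10200001 to 10300000 and 2L 10300001 to 10400000 adjoin and held 14 each, and 3L 9400001 to 9500000 held 14 that covered 54.02% of it. The fifth, 2L 200001 to 300000, held 13, as did another 2 windows that ranked after it by arm and start. None of these 5 windows held any of the 20 highest-scoring clusters, and the highest score in them was 1.51. Across all windows, the numbers of clusters in replicates 1 and 2 correlated with a Spearman rho of 0.939 and a Pearson r of 0.932. Windows are not independent replicates.

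**Figure D3:**
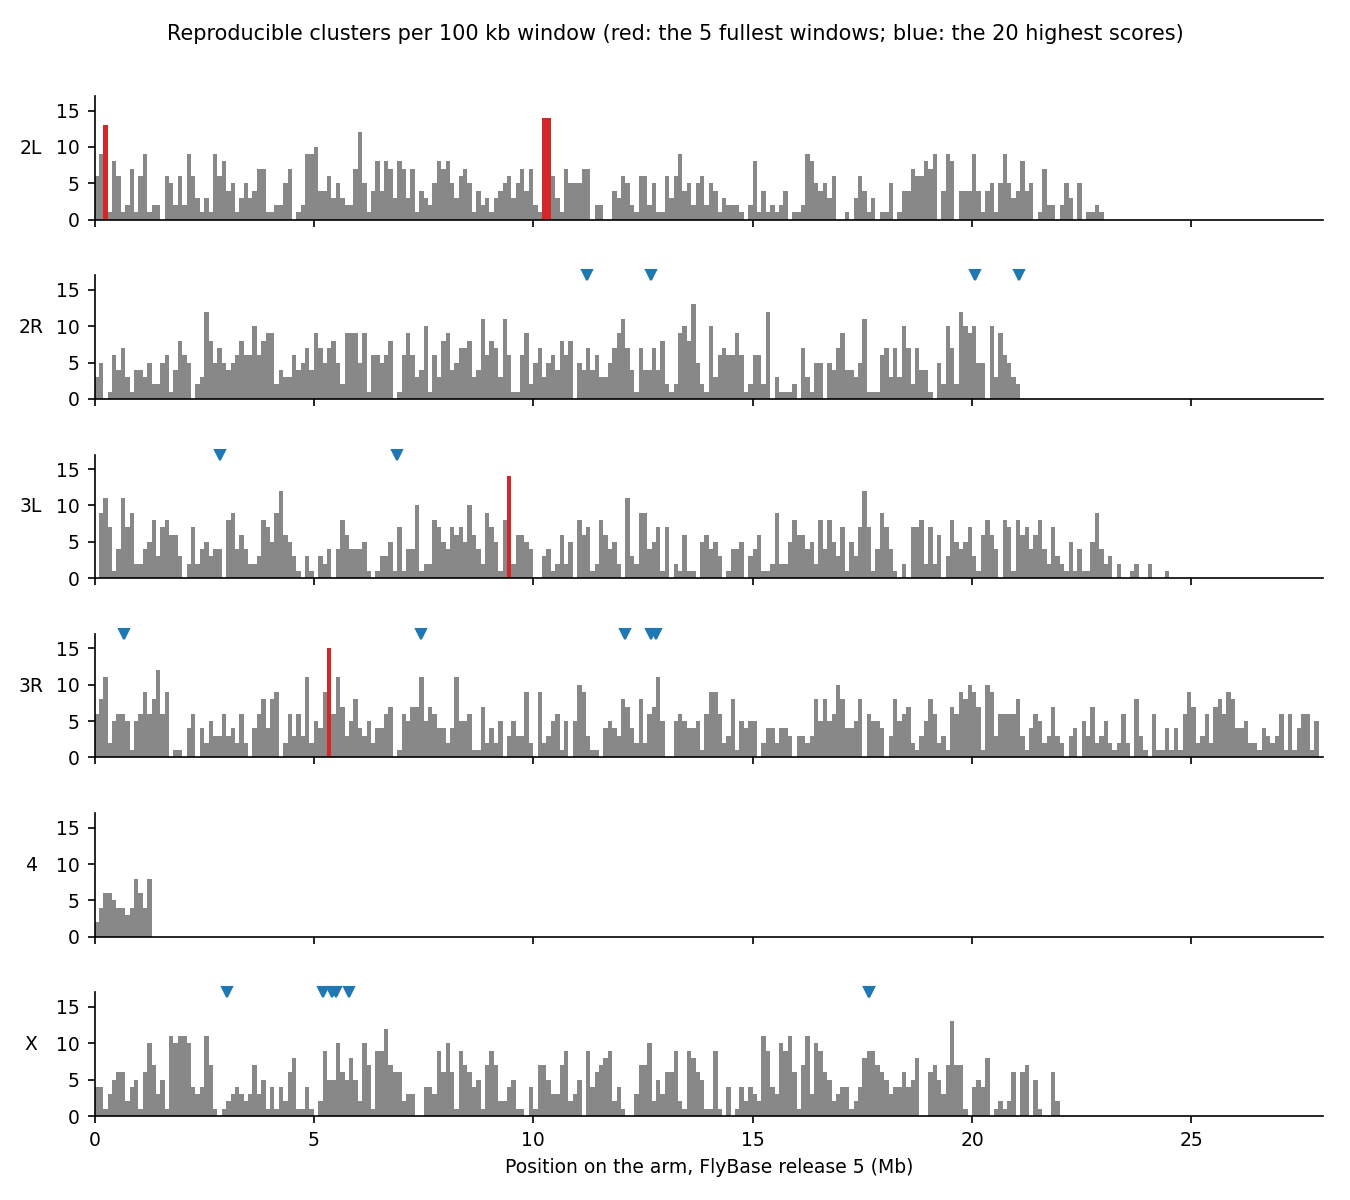
Number of reproducible clusters in each 100 kb window (bars, y axis 0 to 17) along the 6 main arms (x axis, position in Mb of FlyBase release 5). Red bars are the 5 fullest windows, with 13 to 15 clusters, and blue triangles are those of the 20 highest-scoring clusters that lie on these arms.

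Whether the X held more Sfmbt clusters per Mb than the autosomes depended on which clusters were counted. In the reproducible set no difference was detected. The X had 1025 reproducible clusters, or 45.7 per Mb, and the autosomal arms had 4380, or 44.7 per Mb. The ratio was 1.02, inside the range of 0.93 to 1.07 that held 95% of 10000 random placements (two-sided permutation of positions, p = 0.53). With an overlap in replicate 1 no longer required, the ratio was 1.06, at the edge of its random range (permutation p = 0.052). The combined list, made from both replicates, was still the source of those clusters. The following lists were compared only after the data were seen. In the replicates' own lists it was 1.05 in replicate 1 (permutation of 1 Mb blocks, p = 0.44) and 1.11 in replicate 2 (p = 0.11 by permutation of blocks and 0.0060 by random placement). Over all clusters of the combined list it was 1.14 (permutation of blocks, p = 0.016). Strong clusters and covered length differed. Among clusters at or above the combined list's median score the ratio was 1.38, and by base pairs covered it was 1.21, each with a two-sided p of 0.002, the smallest that 1000 placements could give. Placement treats clusters as independent, which makes these p-values too small. Among the large autosomal arms 2R had the most clusters per Mb in both replicates, and 2L the fewest, at 46.7 ± 0.49 (SD, n = 2). The X was less dense than 2R in every list. It had 55.7 per Mb against 62.1 in replicate 1, and 57.4 against 59.9 in replicate 2. These were 75.5 and 76.3 in the combined list, and 45.7 and 51.6 in the reproducible set. Chromosome 4 was also denser than the X in each list. A ratio above 1 is therefore not an excess of the X over each autosomal arm.

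Scores were higher on the X than on the 4 large autosomal arms, a comparison chosen after the data were seen. Chromosome 4 was left out of it. Its median score was 0.926 in replicate 1, against 0.918 on the X, and 0.735 in replicate 2, against 0.922. The median score in the replicates' own lists was 0.92 ± 0.0029 (SD, n = 2) on the X, against 0.72 ± 0.03 on 2L, 0.73 ± 0.02 on 2R, 0.72 ± 0.03 on 3L and 0.74 ± 0.04 on 3R. In the reproducible set the X median was 0.94 and that of these 4 arms 0.74, a difference of 0.20. With whole 1 Mb blocks of sequence reassigned between the X and the other arms, the two-sided permutation p was 0.002, the smallest possible, and the adjusted p was 0.0023. The difference was 0.17 in replicate 1 and 0.22 in replicate 2.

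**Figure D4:**
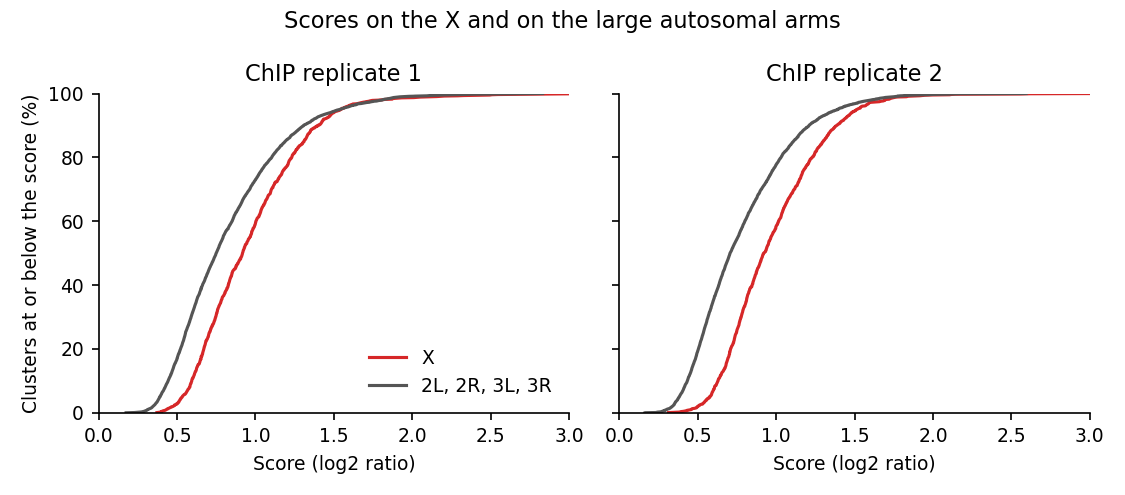
Cumulative share of clusters (y axis, %) at or below each score (x axis, log2 ratio) on the X and on the 4 large autosomal arms, for each replicate. The medians were 0.92 on the X and 0.75 on the autosomal arms in replicate 1, and 0.92 and 0.71 in replicate 2; in replicate 1 the curves meet above a score of 1.5.

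Chromosome 4, the small and largely heterochromatic autosome, was covered far more than any other main arm, which was also compared only after the data were seen. Clusters covered 44.8% ± 1.11 of it (SD, n = 2), against 16.3% ± 0.17 of 2R, 16.2% ± 0.0044 of X and 12.3% ± 0.20 of 2L. In the reproducible set chromosome 4 was covered to 51.6%, which was 2.89 times the share of the next arm, the X at 17.9%. The highest ratio in 10000 random assignments of the clusters to arms was 1.67 (one-sided permutation p = 0.0001, the smallest possible, and adjusted p = 0.00014). Combined-list clusters were counted whole, so this share exceeds the 45.6% and 44.01% of the replicates' own lists. Of the 70 reproducible clusters on chromosome 4, 23 were wider than 10 kb, against 27 of 1025 on the X. In replicate 1's own list 19 of 100 were this wide on chromosome 4 and 8 of 1249 on the X. In replicate 2's these were 12 of 118 and 9 of 1287. The widest reproducible cluster, at 463251 to 508482, spanned 45232 bp with a combined score of 0.89, and the widest clusters of the other main arms spanned 11017 bp on 3L to 32802 bp on 3R. No cluster of any arm was wider than 32129 bp in replicate 1's list or 32177 bp in replicate 2's. Without clusters above 10 kb the covered share of chromosome 4 was 16.5% and that of the X 16.3% (permutation p = 0.34), with the length of those clusters still counted in the arm. With that length also left out, the rest of chromosome 4 was covered to 25.5% and the next arm to 16.6%, a ratio of 1.54 (one-sided permutation p = 0.002). The highest random ratio there was 1.69. Reassigning clusters to arms treats them as independent, which makes these p-values too small. Those wide clusters on chromosome 4 had a median score of 0.89 in the reproducible set, against 1.11 for clusters of this size on the other main arms.

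**Figure D5:**
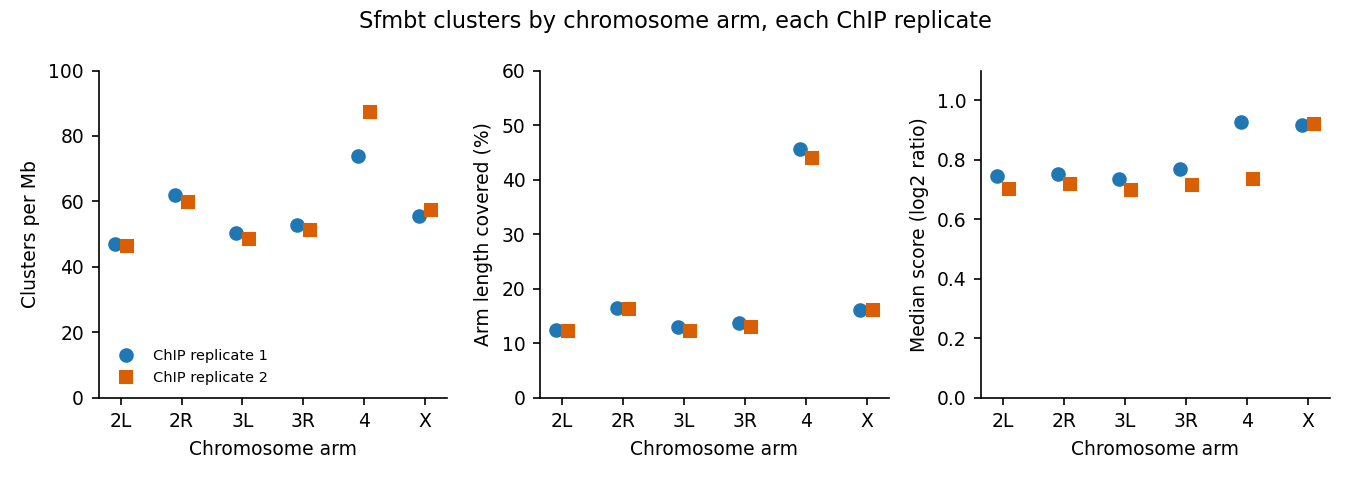
Clusters per Mb, share of the arm covered (%) and median score (log2 ratio) on each main arm, with 1 point for each ChIP replicate. Chromosome 4 was covered to 45.6% and 44.01%, above all other arms in both replicates, and its median score was 0.93 in replicate 1 and 0.73 in replicate 2.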

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

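Among the tests in this part, 6 were written after the values they measure had been seen: the shared scores, the smallest width, the remaining length of chromosome 4, the scores of its wide clusters and both comparisons of single replicates.

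The combined list held 1590 clusters that neither replicate's list had. Those on the main arms entered the X density over all combined-list clusters, and none entered the tests on the reproducible set. They were short, with a median width of 1305 bp, and 125 of them (7.86%) lay outside the main arms. Exact scores were shared with another cluster by 39.1% of them and by 8.30% of the reproducible clusters, a difference of 30.8 percentage points, as ratios of small whole numbers would give. What those numbers count is not stated, so whether these are windows of few reads is open. The smallest width was 1001 bp in the combined list and 1301 bp in the replicate lists, and 49.5% of these clusters were shorter than 1301 bp, so a change in smallest width leaves the others unaccounted for. A missed neighbour is argued against too, since only 20.2% had a replicate cluster within 1 kb. No biological explanation was tested.

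Outside the main arms, 88 reproducible clusters lay on heterochromatic and unplaced sequence, which the tests by arm left out. There were 27 on 2RHet, 24 on U, 20 on 3LHet, 10 on 3RHet, 4 on XHet and 3 on 2LHet, and 0 on YHet and Uextra. The highest score of the whole set was on 3RHet, at 4.52.

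Clusters covered 51.6% of chromosome 4, many of them wide. This is not a matter of 1 replicate, since in the lower of the 2 its covered share was 2.71 times that of the next arm. Leaving out clusters above 10 kb gave a ratio of 1.01, but that test keeps their length in the arm and so decides nothing. With their own length also left out, the rest of chromosome 4 was covered to 25.5% against 16.6% for the next arm, a ratio of 1.54 (permutation of arms, p = 0.002). This argues against clusters above 10 kb as the whole pattern, but weakly. Only 47 clusters remained on chromosome 4, and the highest random ratio was 1.69. Clusters were also treated as independent, which makes the p too small. Clusters above 10 kb scored lower on chromosome 4 than elsewhere, by -0.26 in replicate 1 and -0.23 in replicate 2, but their medians of 0.96 and 0.97 were above the medians of the whole lists, 0.79 and 0.76. These values do not decide whether weak diffuse enrichment was joined into wide clusters, and a chromosome-wide difference in chromatin is open and untested.

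The X had higher scores in both replicates, and its median exceeded that of the next large arm by 0.15 in replicate 1 and 0.20 in replicate 2. A higher score needed for a call on the X would by itself remove weak clusters and add no strong ones. Fewer reads there could also change the scores themselves, and depth is unknown, so the test does not address that. Clusters at or above the autosomal 90th percentile of score were denser on the X, by a ratio of 1.60 in replicate 1 and 2.39 in replicate 2 (permutation of 1 Mb blocks, p = 0.002 in both). A higher threshold by itself is therefore not the whole cause, while fewer reads on the X stay open. Clusters below the autosomal median score were sparser on the X, with ratios of 0.647 and 0.431, which a higher threshold would also give, so it stays open as a part. Within 1.5 to 3 kb the difference was still 0.14 in replicate 1 and 0.19 in replicate 2, so clusters wider than 3 kb are not the whole cause either. Widths within that range were not compared between the X and the other arms, so width stays open as a part. The difference narrowed at high scores in replicate 1 and was nearly even in replicate 2. In replicate 1 the 10th percentile was 0.59 on the X and 0.44 on the autosomal arms, and the 90th was 1.40 and 1.31. In replicate 2 these were 0.63 and 0.43, and 1.39 and 1.21. A scaling of ChIP to input that is off for the X and a biological difference of the X were not tested and stay open.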

How the results depend on the processing

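Of 53 alternative settings over 11 results, 44 left the result on its side of the threshold and in its direction, or its count within 1.5 times. Keeping only clusters at or above the median score left 3280 clusters in replicate 1, 3254 in replicate 2 and 4218 in the combined list, by construction. The X to autosome density ratio passed the threshold when only clusters at or above the combined median score were counted (1.38) and by base pairs covered (1.21). Among settings chosen after seeing the data, it did so over all combined-list clusters (1.14, with 1 Mb blocks too) and in replicate 2's own list (1.11), where it did not with 1 Mb blocks; the cause was not tested. Without clusters above 10 kb the coverage ratio of chromosome 4 was 1.01, also chosen after seeing the data. This follows in part from construction, since their length stays in the arm, and the ratio was 1.54 with that length left out. The share of replicate 1 found in replicate 2 ran from 70.0% with midpoints within 250 bp to 87.9%, and the variance to mean ratio from 1.56 in 50 kb windows to 2.46 in 200 kb windows. With an overlap in replicate 1 no longer required, the reproducible set had 6111 clusters, and with none required in replicate 2 it had 6226. Both are looser filters on the same combined list and do not remove a replicate's data. No paired analysis was possible because the inputs have no values of their own here. The alternatives for transcription start sites, gene lists and motifs were not run, for want of a release 5 genome or annotation. Unknown depth limits all lists: a cluster missing from 1 replicate may be one just under its threshold, and the overlap of 69.5% among the lowest scores of replicate 1 is no measure of sites that differ.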

Other observations

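Of the tests in this part, that of the strongest clusters and those of neighbouring scores in the replicates' own lists were written after their values had been seen.

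Neighbouring reproducible clusters lay close together. Of 5399 gaps on the main arms, 20.9% were under 2 kb, against a mean of 10.2% and a highest value of 11.7% over 1000 random placements without overlap (one-sided permutation of positions, p = 0.001, the smallest possible). Another 170 gaps were longer than 100 kb, the longest 461 kb. Gene density and mappability were not controlled for here either. Close pairs may be single sites that the caller split, but the grouping in 100 kb windows remained past its threshold when clusters under 1 kb apart were merged (ratio 1.62).

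The strongest clusters also lay near each other. The starts of 4 of the 20 highest-scoring clusters fell within 595 kb of the X, between 5204780 and 5803374, where the median score of the 40 reproducible clusters was 1.05. In 1000 draws of 18 main-arm reproducible clusters with the same number per arm, the median of the shortest stretch with 4 starts was 4384 kb, and p was 0.010 (one-sided). The number 4 was chosen because of this stretch, so the grouping is a hypothesis only.

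Scores of adjacent clusters were hardly related. The Spearman correlation over 5399 adjacent pairs was 0.060, against a mean of 0.052 with scores permuted within arms (p = 0.26). In the replicates' own lists it was 0.051 in replicate 1 (mean of permutations 0.034, p = 0.071) and 0.080 in replicate 2 (mean 0.071, p = 0.22), so a similarity of neighbours in score was not detected in any of these. Nor were clusters denser in the outer part of all arms: the ratio of the part next to the telomere to the equally long part next to the centromere was above 1 in 2 of the 4 large autosomal arms, at 1.38 on 2L and 1.17 on 3L, and it was 0.94 on 2R and 0.93 on 3R.

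The side of the difference between replicates varied by chromosome. The median of the score in replicate 1 minus that in replicate 2 was 0.04 on 2L, 2R, 3L and 3R and -0.03 on the X. Of the 191 clusters at which replicate 1 was higher by more than 0.5, 160 lay among the 4203 paired clusters of those 4 arms and 23 among the 990 of the X. Replicate 2 was higher by more than 0.5 at 2 clusters of those arms and at 7 of the X. With the median difference over all pairs subtracted, replicate 1 was higher at 144 and 21, and replicate 2 at 4 and 11. The difference between the X and the other arms was not tested.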
